A study of Mus musculus with 2 samples.

How the data were processed

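Nucleoplasmic RNA of mouse bone marrow-derived macrophages was measured in 2 libraries of 1 group, biological replicates 1 and 2. Per the labels, cells of the inbred strain C57BL/6J received 100 ng/ml Lipid A, the membrane anchor of bacterial lipopolysaccharide that Toll-like receptor 4 senses, for 12 h. The ligand was then washed out for 12 h and given again at 100 ng/ml for 30 min. RNA of the nucleoplasmic fraction was depleted of ribosomal RNA and sequenced. Per the labels, library building started from 1 µg RNA in replicate 1 and 500 ng in replicate 2, with a size range of 250 to 400. The labels give the replicates separate biosamples and the same donor identifier. Whether they are separate mice or cultures is not given in the sources used here, so the spread between them can be technical in part.

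Each library came with a gene table, a transcript table in the same layout and a transcript table in another layout. Per the file headers, all are on assembly mm10 with GENCODE M21. The first gene and transcript tables were derived from alignments to the transcriptome (called alignment-based here) and the other transcript table from the read files (called read-based here). The names and versions of the aligner and the quantification tools, the strand setting and any trimming are not given in the sources used here. The deposited gene tables hold expected counts, which are estimated counts that share ambiguous reads among genes and need not be whole. The deposited TPM and FPKM values are normalised for effective length, TPM to a fixed total per library and FPKM to the number of fragments. The deposited credibility bounds describe the estimation error of TPM and FPKM within a library, but do not always hold the deposited value. Rn7sk in replicate 1, for example, had a TPM of 316861 with bounds of 306963 and 308348. The deposited transcript tables also give the percent of each gene's TPM in each transcript, which was recomputed here from TPM. The annotation used here matched all 55536 gene rows, and 86 of these had no transcript in the read-based table.

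The alignment-based tables also hold 26248 tRNA rows, 96 spike-in rows and 1 row for the phage phiX174. These were kept out of library sizes and scaling. The phage row held 1.10% of all counts in replicate 1 and 0.267% in replicate 2, the tRNA rows held 21 and 38 counts, and the spike-in rows held 0 in both. Expected counts of genes were rounded to whole numbers. Gene counts summed to 23846021 in replicate 1 and 20675305 in replicate 2, so that 3 counts, the upper limit that a count of 0 allows, equal 0.126 and 0.145 CPM. The read-based tables held 33095394 and 33056247 estimated counts of genes. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A test of the counts over 15051 genes gave a chi-square of 108 per gene, far above sampling noise, so the counts are not those of 1 library listed again. This does not show separate cultures.

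With 1 group there is no comparison between groups and no p-value is given. Level was described as mean ± SD of TPM over both libraries. For 27 gene lists, the median over members of log2(TPM + 0.1) was set against 10000 random lists of the same size from 14607 protein-coding genes listed above 0, per library. A list was called high above the 97.5th percentile in both libraries and low below the 2.5th in both. Differences between the libraries were log2 ratios, replicate 2 over replicate 1, of counts scaled by TMM factors of edgeR 4.0.16 (0.994 and 1.01) with a prior count of 0.5. Gene ratios were taken at a mean count of 100 or more, with exact Clopper-Pearson intervals at 95%. List ratios were taken over members with a mean count of 10 or more, and set against 10000 random lists matched on mean count in 20 bins. The biological coefficient of variation, the spread between replicates beyond counting, came from edgeR with an intercept-only design over genes with 10 or more counts in both libraries. Transcript tables were compared over genes with TPM of 10 or more and 2 or more transcripts.

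Named genes were the 3 members of each list with the highest mean TPM and, for the immediate early, NF-kB, late inflammatory and interferon lists, the 3 lowest. To these were added the 10 protein-coding and 5 other genes with the highest mean TPM, the 8 largest ratios in each direction, and immediate early or NF-kB genes whose leading transcript differed between the tables. Other genes named below were chosen after their values were seen. Lists, tests, named genes and most alternatives were fixed before the data were examined. Of the 125 gene records this rule gave, 43 overlap another gene with counts on either strand, among them both Rmrp records, Malat1, Neat1, Xist, Junb, Zfp36, Cxcl10, B2m, Cd274, Ctsd and Irf5. As the strand setting is not given in the sources used here, their values can include reads of the other gene, and only some are marked below. Genes that share sequence with a copy are likewise uncertain.

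The calculations were tested on simulated data. With the spread set to 0.15 for every gene, edgeR recovered 0.149 over 14112 genes. A spread that differs from gene to gene was not simulated. For the replicate ratios, counts of 9675 genes were simulated with the measured spread and 200 genes changed. Of those changed 4-fold, 100% lay beyond 2-fold, as did 44.8% of those changed 2-fold, 14.9% of those changed 1.5-fold and 3.36% of the unchanged. For list ratios over 15051 genes, 6.4% of 1000 unchanged lists of 20 genes lay outside the central 95% of random lists, as did 94.3% when shifted by 0.5 on the log2 scale. These lists were drawn at random from genes simulated independently. They do not show how often lists of genes that move together would lie outside. Alternatives were DESeq2 1.42.0 size factors, library size, other pseudocounts, filters and units, the read-based table and each library alone. Further alternatives, chosen after seeing the data, were other backgrounds for random lists, removal of GC and length trends, and leaving out mitochondrial and overlapping genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.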

Results

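The data describe RNA of the nucleoplasmic fraction of mouse macrophages that had met Lipid A before and met it again for 30 min. There were 2 biological replicates of this 1 condition, with 23846021 and 20675305 gene counts in replicates 1 and 2. Values are TPM as mean ± SD (n = 2) unless said otherwise. In all, 11040 genes had a TPM of 1 or more in both libraries, of which 9220 were protein-coding and 692 long noncoding. Replicate 1 alone had 11618 such genes and replicate 2 had 11914.

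Short structured RNAs took most of the TPM in the alignment-based table. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive (chromosome 9, 78175303 to 78175633), stood at 311353 ± 7789. Rpph1, the RNA of ribonuclease P, stood at 93742 ± 3091, and Rmrp, the RNA of ribonuclease MRP, at 55013 ± 16069. The read-based table gave lower TPM in replicates 1 and 2. It gave 107627 and 137361 for Rn7sk, 29610 and 40881 for Rpph1 and 17352 and 17072 for Rmrp. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA with equal values in the table, stood at 46899 ± 26687 each and are uncertain. The list of 10 small noncoding RNA genes lay above all random lists in both libraries, and 3 of its members were below 1 TPM in both. Malat1, a long noncoding RNA of nuclear speckles (chromosome 19, 5795690 to 5802672), stood at 16806 ± 6840 and was the gene with the most counts, 2360488 and 1885720. Its TPM was higher in replicate 2 (11969 and 21643), but its scaled counts were lower there, at a log2 ratio of -0.14. The SD of TPM is thus not the spread of counts. Neat1, the scaffold of paraspeckles, stood at 687 ± 123 and Xist at 99.3 ± 11.7. The 11 nuclear retained long noncoding RNAs as a list were in the middle, at the 80.8th and 59.8th percentile. By RNA class, misc_RNA genes took 40.6% ± 6.14 of TPM, ribozymes 14.9% ± 1.31 and snRNAs 10.2% ± 0.283, against 20.1% ± 2.49 for nuclear protein-coding genes. By expected counts, nuclear protein-coding genes took 70.8% in replicate 1 (95% Wilson interval 70.8 to 70.8) and 71.0% in replicate 2 (71.0 to 71.0), and long noncoding genes 14.3% and 11.4%. Counts gave misc_RNA genes only 7.32% and 5.43%, ribozymes 2.09% and 1.73% and snRNAs 0.162% and 0.121%. The most abundant gene took 9.51% ± 0.55 of counts, the top 10 took 23.9% ± 0.768 and the top 100 took 40.7% ± 0.182.

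**Figure D1:**
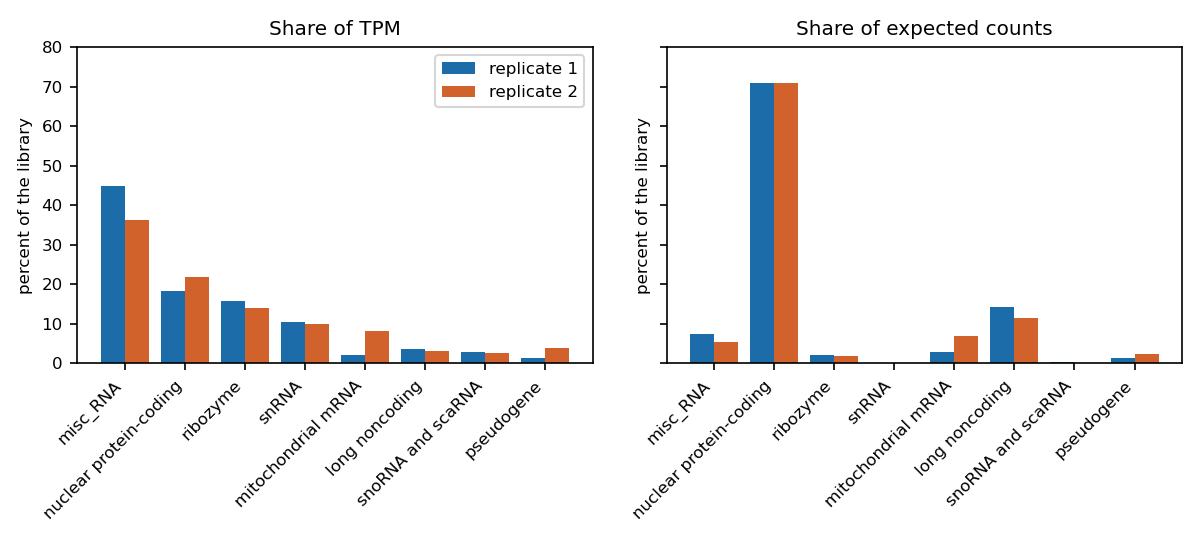
Share of each RNA class in percent of the library, by TPM (left) and by expected counts (right), with 1 bar per replicate. Nuclear protein-coding genes take 20.1% of TPM on average but 70.9% of counts.

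Macrophage identity genes were high, with 19 of 20 at 1 TPM or more in both libraries and a list median of 94.9 and 92.1 TPM. Lyz2 (lysozyme) stood at 1488 ± 658, Ctsd (cathepsin D) at 1407 ± 331 and Ctss (cathepsin S) at 835 ± 211. The most abundant nuclear-encoded mRNAs were Psap (prosaposin) at 2968 ± 313, H2-K1 (a class I histocompatibility heavy chain, of a multigene family and therefore uncertain) at 2553 ± 608 and Fth1 (ferritin heavy chain) at 1965 ± 111. By mean TPM, the other 7 of the 10 highest protein-coding genes were mitochondrial, among them mt-Atp8 at 17638 ± 19722 and mt-Co1 at 12978 ± 7008. The order of these 2 is uncertain. The short mt-Atp8 (bases 7766 to 7969) had 2772 and 17892 counts, against 409446 and 660730 for mt-Co1. It lay below mt-Co1 in replicate 1 (3693 against 8023 TPM). The read-based table put it below in both libraries (723 and 8028 against 3109 and 10981). In replicate 1 alone, mt-Cytb (1042) and mt-Nd4 (997), both among the 7, lay below Ctsd (1173) and Actb (1071). The 13 mitochondrial mRNAs as a list lay above all random lists in both libraries. They took 2.81% of counts in replicate 1 and 6.85% in replicate 2, so levels given here may not be of nuclear RNA alone.

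Markers of other cell types were low. The lists of T and NK cell, B cell, neutrophil, dendritic cell, erythroid, mast cell, fibroblast and endothelial markers all lay below the 2.5th percentile in both libraries. The T and NK cell and dendritic cell lists did not in the read-based table. Restricted to members at 1 TPM or more, all 8 lists kept too few members to be tested. Exceptions within them were Cd28 at 32.2 ± 11.9, Cd4 at 19.1 ± 11.1, Vwf at 13.1 ± 1.71, Kdr at 7.89 ± 2.43 and Cd22 at 4.25 ± 0.849. The highest members of other marker lists were S100a9 at 0.905 ± 0.276 for neutrophils, Ccr7 at 1.14 ± 0.438 for dendritic cells, Alas2 at 2.46 ± 0.785 for erythroid cells, Kit at 0.41 ± 0.0141 for mast cells and Col1a2 at 0.07 ± 0.0424 for fibroblasts.

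Immediate early genes, whose transcription needs no new protein, were high in both libraries, with a list median of 48.3 and 59.7 TPM and 17 of 22 members at a mean of 10 TPM or more. Zfp36, which encodes an mRNA decay factor (chromosome 7, 28376784 to 28380253), stood at 374 ± 81.0, Klf6 at 182 ± 43.0 and Junb at 171 ± 2.11. By mean TPM, the lowest members were Fosb at 1.95 ± 2.24, Myc at 2.25 ± 0.424 and Klf2 at 4.62 ± 0.0283. In replicate 1 alone, Nr4a1 (1.95) lay below Klf2 (4.6). Early NF-kB targets were higher still, with a median of 86.8 and 122 TPM and all 24 members above 10 TPM. Tnf, a cytokine (chromosome 17, 35199381 to 35202007), stood at 662 ± 131, Cxcl2, a neutrophil chemokine, at 431 ± 90.4, and Ccl3 at 313 ± 97.7. The lowest were Relb at 13.8 ± 2.41, Bcl3 at 17.2 ± 0.735 and Ptgs2, the inducible cyclooxygenase, at 23.6 ± 15.8.

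Late inflammatory cytokine and effector genes were spread over a wide range, and the list was in the middle, at the 69.4th and 31.9th percentile. Of its 20 members, 4 had a mean of 100 TPM or more and 6 were below 1 TPM in both libraries. Ccl5 stood at 739.9 ± 49.2, Cxcl10 at 401 ± 89.1 and Ccl7 at 239 ± 5.34. At the other end, Lif stood at 0.04 ± 0.0424, Il12a at 0.08 ± 0.0849 and Csf3 at 0.165 ± 0.0212, each on 7 counts or fewer per library. Il6, chosen after its values were seen, stood at 4.09 ± 2.65.

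Interferon stimulated genes formed the highest of the inducible lists, with a median of 168 and 134 TPM and 17 of 22 members at a mean of 100 TPM or more. Rsad2, which encodes the antiviral enzyme viperin (chromosome 12, 26442746 to 26456452), stood at 722 ± 148, Ifit2 at 654 ± 74.2 and Mx1 at 508 ± 210. The lowest, Oas1a, Usp18 and Ifih1, still stood at 54.1 ± 11.1, 57.9 ± 11.0 and 67.3 ± 2.79.

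Antimicrobial and pattern receptor genes were high as a list, with Saa3 (an acute phase protein) at 672 ± 33.5, Acod1 (the itaconate-forming enzyme) at 527 ± 50.2 and Clec4e at 368 ± 152, while 4 of 15 members were below 1 TPM in both libraries. The list named negative regulators of Toll-like receptor signalling was high too. Its members with the highest mean TPM were Cd274 at 287 ± 74.3, Tnip3 at 230 ± 5.92 and Socs3 at 82.6 ± 1.21. Whether each member, Cd274 among them, restrains this signalling was not tested. Among TLR4 signalling components, all 22 were at 1 TPM or more in both libraries, with Cd14, the lipopolysaccharide co-receptor, at 182 ± 68.6, Tbk1 at 53.7 ± 1.85 and Irf5 at 35.7 ± 0.417. Alternative activation genes were near the low end, at the 6.01st and 5.35th percentile, with Il4ra at 41.9 ± 0.375, Clec10a at 4.97 ± 0.926 and Pparg at 3.69 ± 0.955.

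Of the remaining lists, housekeeping genes (Actb at 1798 ± 1029, B2m at 788 ± 447, Eef1a1 at 382 ± 108), ribosomal protein genes (Rps24 at 178 ± 123, Rpl41 at 128 ± 44.9, Rpl10 at 95.1 ± 0.651), cholesterol and LXR genes (Apoe at 363 ± 2.93, Abca1 at 102 ± 32.6, Scd2 at 96.5 ± 56.6) and glycolysis and hypoxia genes (Pkm at 106 ± 32.7, Vegfa at 48.4 ± 11.5, Aldoa at 44.0 ± 8.65) were high. Replication dependent histone genes were low, with 32 of 67 below 1 TPM in both libraries. By mean TPM, Hist2h2aa2 was the highest at 13.0 ± 11.2, but it overlaps Gm20632 and is uncertain. In replicate 2 alone it (5.05) lay below Hist3h2a (11.9) and Hist1h4m (8.62). Cell cycle genes (Pcna at 21.5 ± 3.8, Mki67 at 11.8 ± 2.35, Mcm6 at 5.15 ± 0.608) and snoRNA host genes (Gas5 at 56.3 ± 2.11, Zfas1 at 44.5 ± 14.1, Snhg1 at 16.9 ± 4.36) were in the middle. In total 13 of 27 lists were high, 9 low and 5 in neither class.

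**Figure D2:**
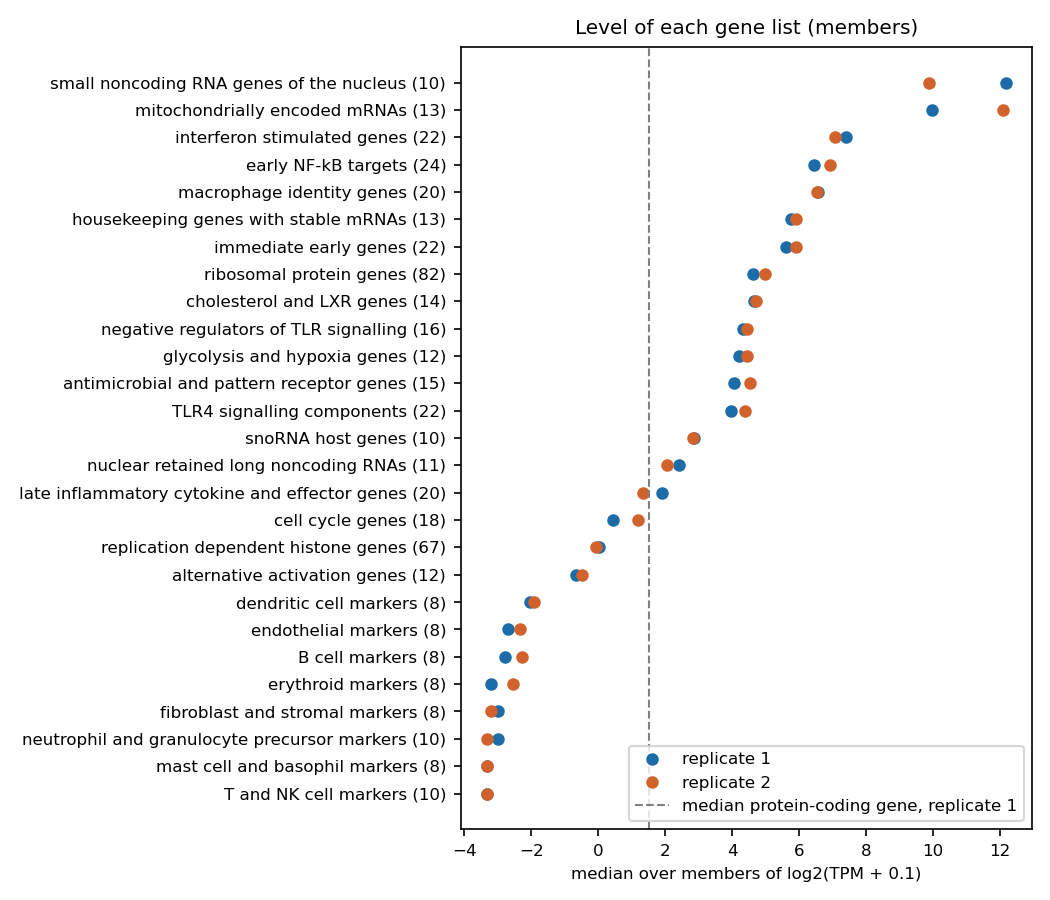
Median over members of log2(TPM + 0.1) for each gene list, with 1 point per replicate and the number of members in parentheses. The dashed line marks the median protein-coding gene of replicate 1, 2.79 TPM. Interferon stimulated genes sit at 168 and 134 TPM.

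The replicates were then set against each other. Across 12492 genes with TPM of 1 or more in either library, log2(TPM + 0.1) had a Pearson correlation of 0.884 and a Spearman correlation of 0.929, where genes are not independent replicates. The Pearson value moved with the pseudocount, from 0.811 at 0.01 to 0.935 at 1. On counts scaled to library size (CPM), which are not normalised for length, the values were 0.97 and 0.978, and the cause of this rise was not tested. The biological coefficient of variation was 0.222 over 14345 genes by edgeR, and 0.105 as DESeq2's median gene-wise value. TPM of nuclear protein-coding genes was higher in replicate 2 by a median of 0.26 on the log2 scale, a 1.2-fold shift, against 0.01 for TMM-scaled counts. Credibility intervals of TPM did not overlap for 4029 genes higher and 922 lower in replicate 2, and after scaling out this shift for 1898 and 2177. For some named genes TPM and scaled counts differed by more than this shift. Actb had a TPM of 1071 and 2525 in replicates 1 and 2, against a 1.38-fold rise in scaled counts. Rps24 had 91.8 and 265, against 1.27-fold. The cause was not tested. Ratios below are of scaled counts.

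**Figure D3:**
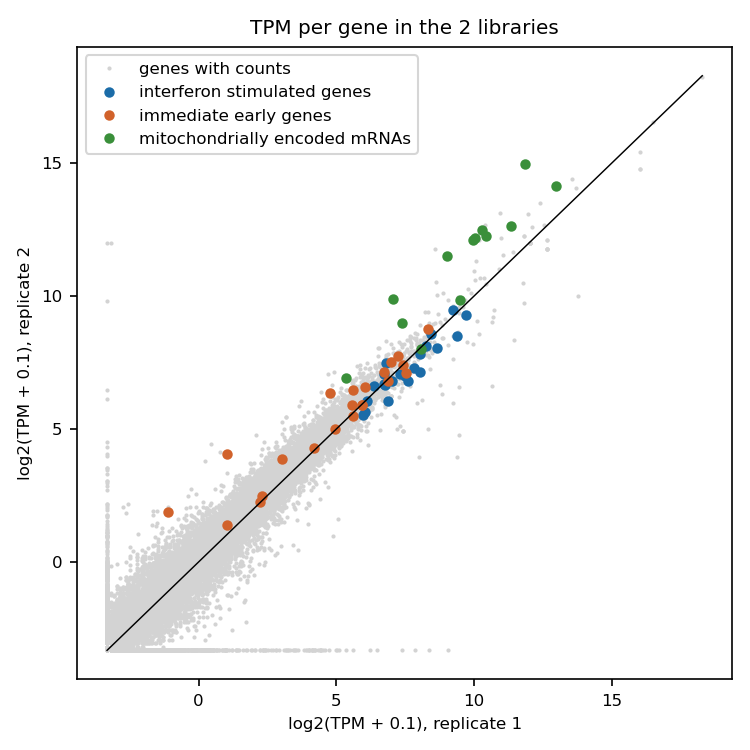
log2(TPM + 0.1) of each gene in replicate 1 (horizontal) and replicate 2 (vertical), with 1 point per gene, the line of equality, and 3 gene lists in colour. The mitochondrially encoded mRNAs lie above the line.

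Mitochondrial mRNAs differed most among the lists that were higher in replicate 2. Their median log2 ratio was 1.53 (100th percentile of random lists), with 12 of 13 members higher and 10 beyond 2-fold. mt-Atp8 had 2772 and 17892 counts, a log2 ratio of 2.88 (counting interval 2.82 to 2.94), and overlaps mt-Atp6. Housekeeping genes were higher by 0.30 (99.5th percentile), with 11 of 13 members higher. Lists lower in replicate 2 were small noncoding RNA genes (median log2 ratio -1.42, which is the value of the copies Rn7s1 and Rn7s2, and -0.79 over the 5 members with a mean count of 100 or more), replication dependent histone genes (-0.64, but -0.26 and inside the random range on the 8 members with a mean count of 100 or more), interferon stimulated genes (-0.54), late inflammatory genes (-0.52) and, on 3 members, endothelial markers (-0.72). Of 22 interferon stimulated genes 2 were higher in replicate 2, Ifit1 and Gbp2, and 4 were beyond 2-fold lower, Mx1, Cmpk2, Isg15 and Mx2, all but Mx1 named after their values were seen. Immediate early genes (0.10, 88.4th percentile) and early NF-kB targets (0.12, 95.7th percentile) lay inside the range of random lists, but above it (99.1st and 97.6th percentile) with GC and length trends removed. In the read-based table they lay inside it, at 0.14 (96.0th percentile) and 0.00281 (53.3rd percentile). Of 16 late inflammatory genes tested, 12 were lower in replicate 2, 4 of them beyond 2-fold (Cxcl11, Nos2, Ifnb1 and Edn1), and the 4 that were higher, Il6, Il10, Il12b and Il23a, all exceeded 2-fold, these genes being named after their values were seen. These 7 of 22 lists differ between 1 library and another, with no replicate check.

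**Figure D4:**
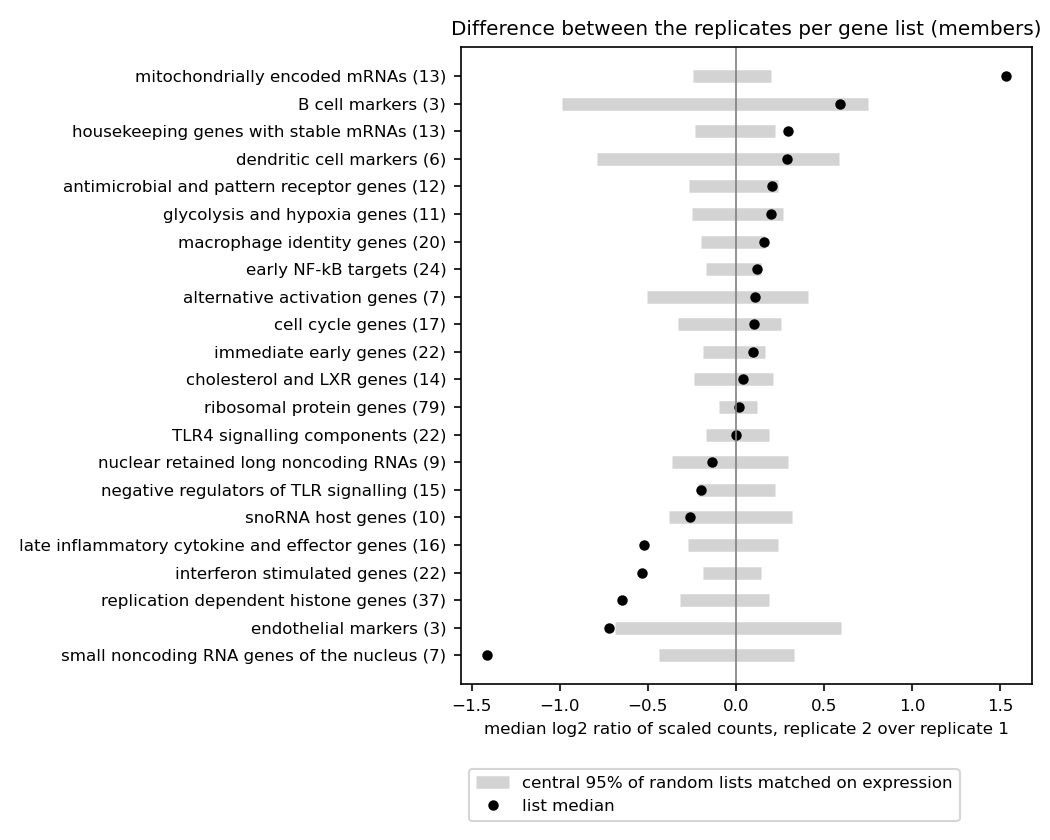
Median log2 ratio of scaled counts, replicate 2 over replicate 1, for each gene list (points, members tested in parentheses), with the central 95% of random lists matched on expression (grey bars). Mitochondrial mRNAs lie at 1.53 and interferon stimulated genes at -0.54, both outside their bars.

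Among 9675 genes with a mean count of 100 or more, 158 were beyond 2-fold higher and 177 beyond 2-fold lower in replicate 2, 3.46% in all. Simulated unchanged genes gave 3.36%, but with the spread estimated from these same libraries, so the closeness is built in and is no value for the absence of change. Among the largest ratios were Cdkn1c, a cell cycle inhibitor (chromosome 7, 143458339 to 143461050), with 23 and 185 counts and a log2 ratio of 3.17 (2.57 to 3.89), and Fosb (chromosome 7, 19302696 to 19310051), with 43 and 312 counts and a ratio of 3.03 (2.58 to 3.54). The pseudogenes Rps6-ps4 (3.14) and Gm28439 (2.92, a copy of mitochondrial sequence on chromosome 1) share sequence with other genes and are uncertain. Gm37376, inside Malat1, had 0 and 5894 counts in the alignment-based table but 18212 and 39250 in the read-based table. The snRNA copies Gm24924 and Gm26244 had 0 and 677 counts each, their TPM intervals overlapped between the libraries, and the read-based table gave Gm24924 0.00264 and 199 counts and Gm26244 95.6 and 67.1. The tables thus differ in direction for Gm26244 and not for Gm24924, and the values of both are uncertain. Lower in replicate 2 were Gm26917 (chromosome 17, 39843013 to 39846341), with 332901 and 28100 counts and a ratio of -3.38 (-3.40 to -3.36), CT010467.1 (-4.28), annotated as ribosomal RNA and overlapping Gm42418, and Snora73b (-3.44), a small nucleolar RNA overlapping Gm17300. B430305J03Rik had 1480 and 0 counts, Gm26759 392 and 0 and Gm49342 353 and 0, each overlapping another gene, against 0 in both libraries, 437 and 59.0, and 966 and 9.67 in the read-based table. Lrrc14b (-5.19) and the long noncoding record of Rmrp (-3.97) also overlap another gene. The strand setting of the counting is not given in the sources used here, so ratios of overlapping genes are uncertain. Without mitochondrial and overlapping genes, an alternative chosen after seeing the data, 78 genes were beyond 2-fold higher and 65 lower among 4653.

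The 2 transcript tables of each library were compared last. Transcript TPM had a Spearman correlation of 0.599 ± 0.0105 between the tables (n = 2), across transcripts that are not independent replicates. The leading transcript was the same in both for 74.6% ± 6.38 of genes (2426 of 3463 in replicate 1 and 3130 of 3958 in replicate 2). At gene level, the read-based TPM of protein-coding genes was lower by a median of -0.90 in replicate 1 and -0.40 in replicate 2 on the log2 scale. TPM has a fixed total, and a few short genes without alignment-based counts held 62.0% and 43.6% of read-based TPM. Lower TPM here is thus not fewer counts, as the read-based tables held 33095394 and 33056247 gene counts against 23846021 and 20675305. Of 32 immediate early and early NF-kB genes assessed, 11 had another leading transcript in the read-based table in at least 1 library, and Csrnp1, Nfkbid, Relb, Bcl3 and Birc3 did in both. For Bcl3, Bcl3-201 (protein-coding) took 57.9% and 61.7% of the gene in the alignment-based table, and Bcl3-204 (a processed transcript) led the read-based table with 35.8% and 37.1%. For Nfkbid, transcript Nfkbid-203 took 70.1% and 65.3% in the former and 27.0% and 30.7% in the latter. Dusp1, Tnfaip3 and Pim1 differed in replicate 1 and not in replicate 2, and Nfkbie in replicate 2 and not in replicate 1. Nr4a1 and Maff differed in replicate 2 and were not assessed in replicate 1, where they stood at 1.95 and 8.08 TPM.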

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

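Of the tests in this part, only that of GC and length was chosen before its result was seen. No biological explanation was tested for any pattern, since the design holds 1 group. RNA input differed between the libraries and cannot be separated from them.

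Counts outside the genes were above the limit that a count of 0 allows. The phage phiX174 took 1.10% of counts in replicate 1 and 0.267% in replicate 2, and tRNA rows held 21 and 38 counts.

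Mitochondrial mRNAs were higher in replicate 2. Reads shared with nuclear pseudogene copies are argued against, since mitochondrial mRNAs and the copies on chromosome 1 summed together still had a log2 ratio of 1.30. Short length inflating TPM does not enter these ratios, which are of scaled counts, so the test of it bears on TPM only. TPM added a median of -0.00555 (-0.0859 to 0.0151 over 13 mRNAs) to the log2 count ratio. This is relative to the 0.27 it added for nuclear protein-coding genes. Carry-over of cytoplasmic mRNA cannot be told apart: ribosomal protein mRNAs had a median of 0.0144, housekeeping mRNAs 0.30, and their nuclear baseline would hide a small share.

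Interferon stimulated genes were lower in replicate 2, at -0.54 and below all random lists, while immediate early genes lay inside the random range at 0.10. The difference of these medians, 0.63, was chosen after the list ratios were seen and mostly restates the interferon median. Removing GC and length trends left the interferon median at -0.53, below all random lists, and the difference at 0.69, which argues against those trends as the whole cause. Whether Fosb, Nr4a1 and Fos carry the immediate early side cannot be told apart, since the difference without them, 0.44, also rests on the interferon genes, and the immediate early median turned to -0.10. A difference in timing or handling of the cultures may remain and was not tested.

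Genes of the ribosomal RNA locus on chromosome 17 had 417727 counts in replicate 1 and 45605 in replicate 2, and 30 of 38 small nucleolar and Cajal body RNAs were lower in replicate 2. More complete ribosomal RNA depletion may account for the locus, as mitochondrial ribosomal RNA was lower too, at -0.62. Whether depletion also accounts for the small nucleolar and Cajal body RNAs, which are not ribosomal RNA, cannot be decided. Their median of -1.50, over the 38 tested of 1558 genes in the class, restates the fall to be explained. Removal of RNAs other than ribosomal RNA by the depletion was not measured. The share of the whole class moved by only -0.27. Its highest gene Gm22009 (20199 and 21995 counts) did not fall, and the class without it moved by -1.28. Loss of short inserts across the whole library at size selection is argued against by the mean fragment length behind the deposited effective lengths. It was lower in replicate 2, by -12.3 bases (-55.3 in the read-based table). Loss of only the shortest inserts cannot be told from this mean, as small nucleolar and Cajal body RNAs held 0.171% and 0.142% of counts. Loss of short RNA before library building stays open.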

How the results depend on the processing

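The alternatives on backgrounds of random lists, GC and length trends and left-out genes were chosen after seeing the data. No paired analysis was possible because there is only 1 group. With 1 library on each side, depth limits ratios to genes with many counts. Causes were not tested unless the setting itself gives them. Fewer genes pass a stricter filter: 5953 were detected at TPM 5. The Pearson correlation was 0.935 with a pseudocount of 1, 0.811 with 0.01, 0.975 with no filter, 0.874 on FPKM and 0.97 on CPM, and the Spearman correlation 0.925 with no filter and 0.978 on CPM. The coefficient of variation was 0.25 with no filter, 0.199 at 100 counts and 0.105 as DESeq2's median gene-wise value. Restricting lists to members at 1 TPM or more left the marker lists of other cell types with too few members to be tested. Of the lists still tested 2 were low, histone genes, which were among the 9, and cell cycle genes, which were gained. The read-based table left 6 of the 9, losing T and NK cell, dendritic cell and histone lists. Random lists of genes at 1 TPM or more gave 11 low lists, the 9 with alternative activation and cell cycle genes. Genes beyond 2-fold higher and lower numbered 543 and 776 at a mean count of 10, 2471 and 3880 with no filter, 41 and 46 at 1000, 738 and 822 at 1.5-fold, and 78 and 65 without mitochondrial and overlapping genes. The read-based table put 11 lists outside the random range, gaining T and NK cell, antimicrobial, glycolysis and macrophage identity lists. Non-overlapping intervals numbered 1963 higher and 2114 lower on FPKM, and 1898 and 2177 after scaling. By expected counts the shares were 70.9% nuclear protein-coding, 12.8% long noncoding, 6.38% misc_RNA, 1.91% ribozyme and 0.141% snRNA; by TPM the top gene took 31.2%, the top 10 63.1% and the top 100 81.4%. The ratio of Gm26244, one of the equal snRNA copies, reversed to -0.55 in the read-based table. High lists numbered 13 or 14 under all alternatives run, and the same 13 were among them. The 7 lists that differed between libraries did so with DESeq2 size factors and in the read-based table. At a mean count of 100, histone genes did not and endothelial markers were too few to test, while macrophage identity genes (0.18), nuclear retained long noncoding RNAs (-0.48, 0.37th percentile) and snoRNA host genes (-0.50) were gained and the small noncoding median was -0.79. Random lists of protein-coding genes gained negative regulators of Toll-like receptor signalling. With GC and length trends removed, 5 of the 7 still differed, immediate early, early NF-kB and macrophage identity genes were gained, and the mitochondrial and small noncoding lists, which hold no nuclear protein-coding genes, were not testable. Each library alone gave 11618 to 11914 detected genes, 13 high and 9 low lists, transcript correlations of 0.591 to 0.606 and the same leading transcript in 70.1% to 79.1% of genes.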

Other observations

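Transcripts annotated as retaining an intron took 19.7% ± 2.82 of the TPM of nuclear protein-coding genes in the alignment-based table and 22.2% ± 2.8 in the read-based table (n = 2). Of 2456 genes with such a transcript and TPM of 10 or more in both libraries, 237 had 50% or more of their TPM in it in both libraries and both tables. Among them were Tnip3, at 89.9% and 85.7% in the alignment-based table, and Cd83, at 84.5% and 81.9%. Lilrb4a, an inhibitory receptor gene of a multigene family and therefore uncertain, stood at 97.8% and 95.2%. These genes were chosen after their values were seen. In nucleoplasmic RNA, reads from unspliced precursor RNA cannot be told here from reads of a transcript that keeps its intron.

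The read-based tables gave large values to short genes with 0 counts in the alignment-based table. Gm23935, Gm24245 and Gm24270, miRNA records of 57 bases with equal values, had 247486 and 69574 read-based counts each. The processed pseudogenes Gm12895 and Gm12896, of 226 bases, had 423573 and 424815 counts in replicate 1 and 443216 each in replicate 2. Such genes, 6 in number at more than 40000 counts in either library, held 62.0% and 43.6% of read-based TPM but 4.81% and 3.44% of read-based counts.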
